A study of Homo sapiens with 9 samples.

How the data were processed

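Cytoplasmic extract was made from KG-1a cells by lysis in a hypotonic buffer, per the labels' protocols. For each IP, 1 mg of extract was held for 1.5 h with beads carrying an antibody to hnRNP K or an unrelated control, and the input RNA came from 100 µg of extract. Libraries were made from total RNA depleted of ribosomal RNA with a kit that keeps the strand, from 500 ng of input RNA or 10 µl of IP RNA, per the labels' protocols. The source label names the line KG-1 and the titles and the design text name it KG-1a.

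The submitters' processing notes name bcl2fastq, STAR 2.5.2b, featureCounts, Subread 1.5.1, DESeq2 1.10.1 and the genome build hg38, with no role or order. The gene annotation, the strand setting of the counting and the use of the ERCC spike-ins (synthetic RNAs added in known ratios) are not given in the sources used here. Overlapping and antisense genes can therefore share reads, and so can near-identical copies such as histone genes.

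The authors deposited 2 tables, named for hnRNP K IP against control IP and against input. Both had identical content, so 1 was used and its comparison group was left open. The deposited signal columns hold the mean normalized count of each group, per the file headers. The deposited log2 columns hold the log2 fold change of the hnRNP K IP over the comparison group and its standard error, per the file headers. The deposited score column is the test statistic, and the deposited p-value columns hold the p-value and the adjusted p-value, per the file headers. Tested on the file, log2 fold changes are shrunk toward 0. The median difference from the log2 ratio of the means was 0.00487 over genes with a mean above 1000, and the median ratio was 0.588 below a mean of 10. Single rows with a high mean can be shrunk too, as spike-in ERCC-00130 is in the authors' deposited table (3.55, where the log2 ratio of its means is 4.21).

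The table has 58325 rows, of which 92 are ERCC spike-ins and 58233 are genes. Reads were present for 30606 genes, and 23214 genes and 70 spike-ins have an adjusted p. ERCC rows were left out of all gene counts, while the counts of recovered rows and reads below include them. Of all rows, 36918 matched a symbol or synonym in RefSeq on GRCh38.p14, the assembly hg38 stands for, which gave biotypes and coordinates.

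The design planned tests per library if the files held counts or normalized values per library, and otherwise a description of the authors' comparison with no test of its own. The table holds means alone, so the authors' fold changes and adjusted p-values are the main result. Whole reads per library were recovered as an alternative chosen after seeing the data. Each mean is a sum of 3 whole numbers, each times a fixed step, and the steps were read from genes with 1 read. For means of up to 10000 the 15 printed digits fix the whole numbers. A single solution was found for all 25845 rows above 0 of the hnRNP K IP column and all 28762 of the comparison column at or under that limit. Above it lay 504 and 320 rows. On simulated means of known reads, 300 of 300, 300 of 300, 60 of 60 and 16 of 16 were recovered in 4 ranges of the mean, with 0 wrong. The size factors implied by the steps were 0.840, 0.808 and 0.798 for hnRNP K IP libraries a, b and c and 1.47, 1.19 and 1.16 for the comparison libraries. Between libraries of a group, chi-square per gene was 4.30 to 50.9, so no pair agreed within sampling noise.

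Recovered reads were divided by the size factors and tested as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with a trend, for 15303 genes with a mean of at least 10. Fold changes on that scale understate changes of low genes. On simulated data over 15303 genes, 99% of 2-fold and 100% of 4-fold changes were recovered with 7 false calls among the unchanged genes. The simulated means and spread came from the comparison libraries alone. Chi-square per gene was 10.3 to 50.9 between hnRNP K IP libraries and 4.30 to 11.2 between comparison libraries. The simulation may therefore overstate the recovery and understate the false calls in the real data. Of 10595 genes called in the authors' deposited table and tested by limma, 10148 (95.8%) were called the same way and 0 the opposite way.

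The 23 gene lists were fixed before the data were examined. Each was tested with camera on the deposited statistic with a correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Tests with an estimated correlation and fry ran on recovered reads, which leaves out genes above the limit. On simulated data over 23214 genes, a planted list of 40 genes was called, and 8 of 200 random lists passed 0.05 unadjusted. The statistics were shuffled over genes, so members of these lists were not correlated. The simulation cannot show that a correlation of 0.01 is right for real lists, where the estimate reached 0.753 in mitochondrial mRNAs. The test with an estimated correlation was not simulated. As an alternative chosen after seeing the data, protein-coding genes with a length in RefSeq were put in 20 bins of genomic length, and the median statistic of the bin was taken off before camera. It covered 19 lists with a length for at least 80% of tested members, which leaves out mitochondrial mRNAs and noncoding RNAs. For list medians with bounds, genes at 0 in a group were set at a floor of 3 reads over the group, and these medians equalled the plain medians to 2 decimals except in HLA class II (1.35 against 1.44).

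Named genes were HNRNPK, the 8 largest rises and 5 largest falls among genes past 0.05, protein-coding where RefSeq gave a biotype, whose libraries do not overlap between groups and whose mean is at least 10 CPM in the higher group, the 2 members of each list with the smallest adjusted p, and any member of the list of mRNAs described before for hnRNP K. Genes above the recovery limit cannot be checked for overlap and were passed over in the first part of that rule. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used elsewhere. Alternatives covered the pseudocount, the low-value filter, scaling, library weights and each library left out. A planned test of C-rich motifs in untranslated regions was not run, since transcript sequences were not used here.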

Results

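RNA bound to the protein hnRNP K was collected by immunoprecipitation (IP) from cytoplasmic extracts of KG-1a cells and sequenced. KG-1a is a human acute myeloid leukemia line that came from bone marrow and keeps features of early progenitor cells. hnRNP K is a nuclear and cytoplasmic RNA-binding protein whose KH domains favour C-rich stretches. The series holds 9 samples in 3 groups of 3, namely the hnRNP K IP, an IP with a control unrelated to hnRNP K, and the input RNA of the extract. Each group had 3 independent biological replicates, per the labels.

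The question put by the design is which RNAs come down with hnRNP K, over what sticks to a control IP and over what the extract holds. The tables for these 2 comparisons had the same content byte for byte, so 1 comparison was described. Its numerator is the hnRNP K IP. Whether its other side is the control IP or the input is not settled, and it is called the comparison group throughout. ERCC spike-ins made up 2.20% of the summed signal of the hnRNP K IP and 0.157% of that of the comparison group. If each library received the same amount of spike-in, this argues against a control IP that brought down less RNA than the hnRNP K IP. The amount added is not given in the sources used here, so these values do not decide between control IP and input. The control IP against the input, and the overlap of both enrichments, were not analysed here.

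The authors' deposited table gives a mean per group and no value per library. Whole reads per library were recovered from those means for genes and spike-ins with a mean of at most 10000. These reads came to 14799229, 13122962 and 14148992 in hnRNP K IP libraries a, b and c, or 54.4% of the summed signal of that group. They came to 25770994, 20770087 and 20742603 in the comparison libraries, or 70.3% of the summed signal. The letters carry no replicate number.

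By the authors' size factors, the hnRNP K IP held more mitochondrial mRNA and more replication-dependent histone mRNA than the comparison group, relative to other RNA. It also held more mRNA of several blood cell surface proteins, and less of the long noncoding RNAs held in the nucleus. The list tests behind this were past 0.05 at a preset correlation. They were not with an estimated correlation, over the members in the fit to recovered reads (adjusted p = 0.691 in each of these 4 lists). ERCC spike-ins also rose, with a median log2 fold change of 3.57 in the authors' deposited table (4.19 as plain log2 ratio of the means). The list medians there were 3.74 for mitochondrial mRNAs, 1.00 for histones and 0.77 for surface proteins. Short genes rose in general, and against protein-coding genes of the same genomic length the surface protein list kept its call (camera adjusted p = 0.00771) and the histone list did not (camera adjusted p = 0.0613). In the authors' deposited table, MT-ND1, a subunit of respiratory complex I, rose 19.2-fold (log2 fold change 4.26, SE 0.18, adjusted p = 5.15e-125). The T-cell and progenitor surface protein CD7 rose 14.2-fold in the authors' deposited table (log2 fold change 3.82, SE 0.14, adjusted p = 2.22e-160). The mitotic motor protein CENPE was lower in the authors' deposited table (log2 fold change -3.28, SE 0.41, adjusted p = 1.58e-14), and so was MALAT1, an abundant RNA of nuclear speckles (log2 fold change -2.37, SE 0.21, adjusted p = 5.75e-29). The mRNA of HNRNPK itself, on chromosome 9 at 83968083 to 83980615, had a log2 fold change of -0.48 (SE 0.25) in the authors' deposited table and missed the threshold (adjusted p = 0.0936).

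The authors' deposited table calls 12419 of 23214 tested genes at an adjusted p of 0.05, with 5962 higher and 6457 lower in the hnRNP K IP. That balance is set by the scaling, since limma on recovered reads scaled by ERCC spike-ins called 1 gene higher and 14976 lower. A change of at least 2-fold was met by 3548 genes higher and 3787 lower in the authors' deposited table. A change of at least 4-fold was met there by 967 genes higher and 1062 lower. Of 11934 called genes with recovered reads, 11695 (98.0%) had no overlap between the 3 libraries of each group. The share was 62.1% over all 22628 tested genes with recovered reads, and chance gives 10%.

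The 8 largest rises under the rule for named genes included 4 mitochondrial mRNAs. Beside MT-ND1 these were MT-ND4L, MT-ND2 and MT-CYB, with log2 fold changes of 4.07, 4.01 and 3.91 in the authors' deposited table. The other rises were AC120024.1, which had no match in RefSeq (log2 fold change 4.20, SE 0.28), CD7, the zinc finger gene ZNF358 (log2 fold change 3.87, SE 0.17) and the endoplasmic reticulum protein gene REEP6 (log2 fold change 3.82, SE 0.15), as the authors' deposited table gives them. CD7 lies on chromosome 17 at 82314873 to 82317608, ZNF358 on chromosome 19 at 7513880 to 7521025 and REEP6 on chromosome 19 at 1491181 to 1497927. In recovered normalized counts, CD7 stood at 6382 ± 614 (SD, n = 3) in the hnRNP K IP and 442 ± 68.6 (SD, n = 3) in the comparison group. REEP6 stood at 2387 ± 429 (SD, n = 3) against 165 ± 8.73 (SD, n = 3). MT-ND1 stood at 6311 ± 1656 (SD, n = 3) against 318 ± 19.0 (SD, n = 3). The smallest adjusted p in the authors' deposited table, 2.13e-210, belonged to C9orf16 (BBLN in RefSeq, log2 fold change 4.11, SE 0.13), whose mean is above the limit for recovery and which was chosen after its values were seen.

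The 5 largest falls were AC084082.1, AL355488.2, ANKRD10-IT1 and AP001486.2, which had no match in RefSeq, and the kinetochore motor gene CENPE. Their log2 fold changes in the authors' deposited table were -4.14, -4.07, -3.76, -3.33 and -3.28. Among genes that RefSeq lists as protein-coding, the next falls were the centrosome and cilium gene CEP290, the zinc finger gene ZNF117, the Golgi protein gene TRIP11 and the centrosomal scaffold gene AKAP9, a set chosen after its values were seen. These had log2 fold changes of -3.14, -2.85, -2.83 and -2.78 in the authors' deposited table. CENPE is on chromosome 4 at 103105811 to 103198343, CEP290 on chromosome 12 at 88049016 to 88142088 and AKAP9 on chromosome 7 at 91940862 to 92110673. Recovered normalized counts of CENPE were 288 ± 134 (SD, n = 3) in the hnRNP K IP and 3346 ± 401 (SD, n = 3) in the comparison group. Those of CEP290 were 108 ± 52.3 (SD, n = 3) and 1005 ± 87.8 (SD, n = 3), and those of AKAP9 were 416 ± 87.5 (SD, n = 3) and 2925 ± 381 (SD, n = 3).

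**Figure D1:**
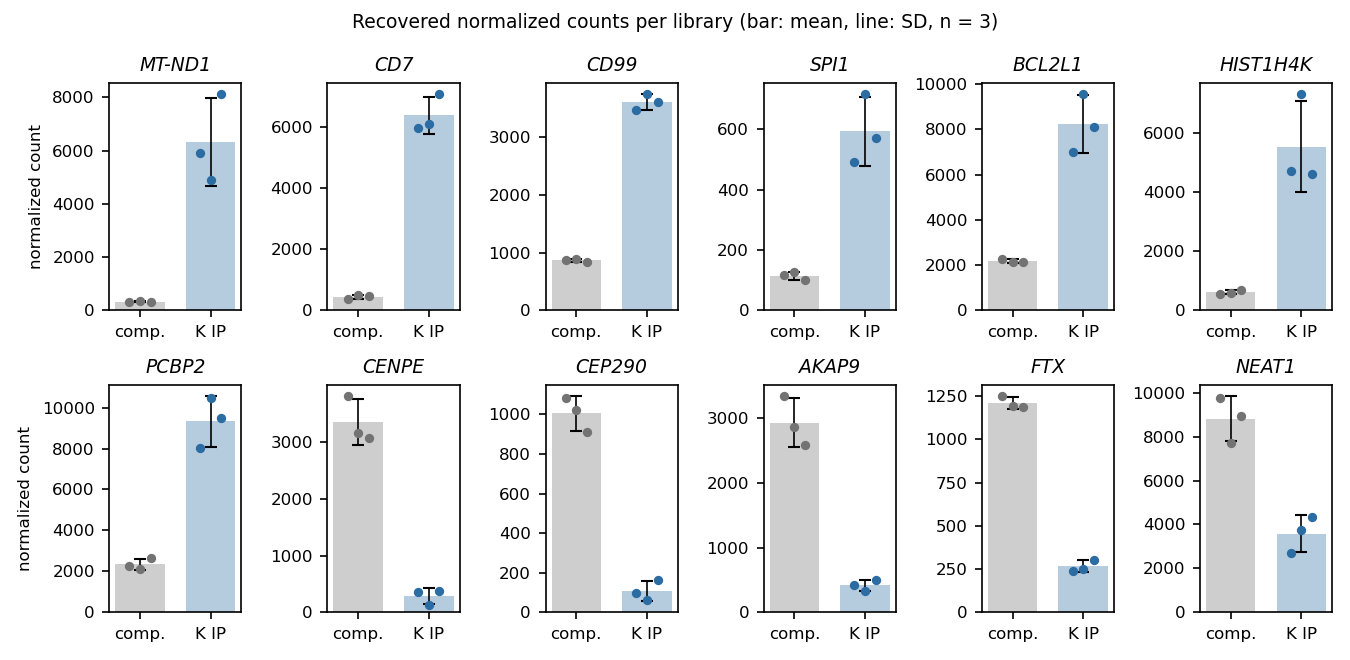
Recovered normalized counts per library (y axis, linear from 0) of 12 genes in the comparison group (comp., grey) and the hnRNP K IP (K IP, blue). Points are libraries, bars are means and lines are the SD (n = 3). The libraries of the groups do not overlap in any of these genes, which the choice required for MT-ND1, CD7, CENPE, CEP290 and AKAP9.

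All 13 mRNAs of the mitochondrial genome rose, with a median log2 fold change of 3.74 in the authors' deposited table (camera adjusted p = 1.68e-30). With an estimated correlation the adjusted p was 0.691, over the 8 mRNAs in the fit to recovered reads. MT-ND3 had the highest log2 fold change, 4.34 (SE 0.18), and MT-ND6 the lowest, 1.61 (SE 0.53, adjusted p = 0.00586), in the authors' deposited table. MT-ND6, chosen after its values were seen, had few reads and did not pass limma on recovered reads. Nuclear genes for the respiratory chain and ATP synthase moved less. There 39 of 77 rose in the authors' deposited table and 10 fell, with a median of 0.31 (camera adjusted p = 0.000247, and adjusted p = 0.916 with an estimated correlation). NDUFA3 and COX8A led them by adjusted p, with log2 fold changes of 2.14 and 1.72 in the authors' deposited table.

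Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, rose in 50 of 54 tested members and fell in 0. The median log2 fold change was 1.00 in the authors' deposited table (camera adjusted p = 2.99e-11). With an estimated correlation the adjusted p was 0.691, over the 18 members in the fit to recovered reads. HIST1H4J and HIST1H4K, H4C11 and H4C12 in RefSeq, had log2 fold changes of 3.23 (SE 0.19) and 3.15 (SE 0.18) in the authors' deposited table. Histone genes are near-identical copies, so the division of reads among them is uncertain.

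Of 56 tested genes for surface proteins of myeloid and progenitor cells, 31 rose and 11 fell in the authors' deposited table, with a median log2 fold change of 0.77. The list passed the camera test (adjusted p = 0.000614), with adjusted p = 0.691 with an estimated correlation. After CD7, the smallest adjusted p was that of CD99, an adhesion protein of leukocytes (log2 fold change 2.06, SE 0.09, adjusted p = 2.8e-107 in the authors' deposited table). The recovered normalized counts of CD99 were 3616 ± 138 (SD, n = 3) against 862 ± 24.9 (SD, n = 3). CD34, the marker of blood stem and progenitor cells, had a log2 fold change of 1.80 (SE 0.12, adjusted p = 2.9e-52) in the authors' deposited table and was chosen after its values were seen.

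Transcription factors of blood stem and myeloid cells rose in 21 of 45 members and fell in 9, with a median of 0.24 in the authors' deposited table (camera adjusted p = 0.0314, and adjusted p = 0.916 with an estimated correlation). RUNX3 and LYL1 led by adjusted p, with log2 fold changes of 1.78 (SE 0.11) and 1.50 (SE 0.10) in the authors' deposited table. Granule and effector proteins of neutrophils and monocytes rose in 8 of 20 members and fell in 2 (camera adjusted p = 0.0037, and adjusted p = 0.691 with an estimated correlation). The protease inhibitor gene CST7 and the lysosomal protease gene CTSD rose by log2 fold changes of 3.33 and 2.98 in the authors' deposited table. The 2 that fell, CYBB and SERPINB1, had values of -0.75 and -0.38 in the authors' deposited table and were chosen after these were seen.

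Markers of other blood lineages were tested as well. Among T and B lymphocyte genes 6 of 13 rose and 0 fell, with a median of 1.16 in the authors' deposited table (camera adjusted p = 0.0299). With an estimated correlation the adjusted p was 0.691, over the 6 members in the fit to recovered reads. CD3E, a chain of the T-cell receptor complex, had a log2 fold change of 3.18 (SE 0.16) and the immunoglobulin heavy chain gene IGHM 2.00 (SE 0.14) in the authors' deposited table. Recovered normalized counts of CD3E were 448 ± 24.1 (SD, n = 3) against 48.1 ± 0.765 (SD, n = 3). Of 6 tested erythroid genes, the erythropoietin receptor EPOR, the transferrin receptor TFR2 and KLF1 rose and CA2 fell in the authors' deposited table. KLF1 and CA2 were chosen after their values were seen, and the erythroid list missed the threshold (camera adjusted p = 0.265). For HLA class II, HLA-DMA and CD74 rose among 5 tested genes in the authors' deposited table (camera adjusted p = 0.62), and CD74 had no recovered read in the comparison group.

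Cytosolic ribosomal protein mRNAs rose in 46 of 79 members and fell in 10, with a median of 0.38 in the authors' deposited table (camera adjusted p = 0.000123). With an estimated correlation the adjusted p was 0.916, over the 8 mRNAs at or under the limit for recovery. RPL28 and RPL29 led by adjusted p with log2 fold changes of 2.36 (SE 0.10) and 2.39 (SE 0.11) in the authors' deposited table. RPLP0, chosen after its values were seen, rose more (log2 fold change 3.01, SE 0.18, in the authors' deposited table) and made up 2.46% of the summed signal of the hnRNP K IP against 0.374% in the comparison group. Actin cytoskeleton and motility genes rose in 19 of 39 members and fell in 6 (camera adjusted p = 0.0147). With an estimated correlation the adjusted p was 0.939, over the 21 members in the fit to recovered reads. PFN1, which binds actin monomers, and WAS, which drives actin branching, had log2 fold changes of 2.55 and 1.87 in the authors' deposited table.

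Among long noncoding RNAs of the nucleus 8 of 12 fell and 0 rose, with a median of -1.24 in the authors' deposited table (camera adjusted p = 0.000123, and adjusted p = 0.691 with an estimated correlation). FTX and KCNQ1OT1 had log2 fold changes of -2.17 (SE 0.13) and -1.90 (SE 0.15) in the authors' deposited table. NEAT1, the scaffold of paraspeckles, was at -1.28 (SE 0.17) there, by the authors' deposited table, and like MALAT1 was chosen after its values were seen. Other regulators of mRNA stability and translation fell in 28 of 51 members and rose in 11, with a median of -0.55 in the authors' deposited table (camera adjusted p = 0.0299, and adjusted p = 0.916 with an estimated correlation). They held opposite changes in the same list. The decapping enzyme gene DCP2 had a log2 fold change of -1.89 (SE 0.11) and ZFP36, whose protein brings about decay of AU-rich mRNAs, 3.20 (SE 0.18) in the authors' deposited table.

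mRNAs of hnRNP proteins and their poly(C)-binding relatives split. By the authors' deposited table, 6 of 30 rose and 13 fell, and the list as a whole missed the threshold (camera adjusted p = 0.842). PCBP2 and RALY had log2 fold changes of 1.98 (SE 0.14) and 1.65 (SE 0.09) in the authors' deposited table. PCBP1 (1.15), PCBP3 (2.15) and HNRNPR (-1.10), chosen after their values were seen, are log2 fold changes from the authors' deposited table.

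mRNAs described before as bound or regulated by hnRNP K rose in 14 of 29 tested members and fell in 6 in the authors' deposited table, with a median of 0.28 (camera adjusted p = 0.289). SPI1, which encodes the myeloid factor PU.1, had a log2 fold change of 2.35 (SE 0.18) and the survival gene BCL2L1 1.91 (SE 0.13) in the authors' deposited table. The uncoupling protein gene UCP2, the cell cycle inhibitor gene CDKN1A, CEBPA and MYC rose with log2 fold changes of 1.76, 1.71, 1.07 and 1.06 in the authors' deposited table. ALOX15, the lipoxygenase mRNA held silent by hnRNP K in erythroid precursors, had 1.57 (SE 0.67, adjusted p = 0.0377) in the authors' deposited table. Its recovered normalized counts were low, at 6.54 ± 1.90 (SD, n = 3) against 1.59 ± 0.195 (SD, n = 3). YES1, BRCA1, MDM2 and MAP3K7 were lower, with log2 fold changes of -1.52, -1.41, -1.30 and -1.09 in the authors' deposited table. RPS19, STAT3 and PTGS2 did not pass the test in the authors' deposited table, with log2 fold changes of 0.12, -0.13 and 0.08.

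The remaining 8 lists missed the threshold. G2 and M phase genes had 8 rises and 17 falls among 36 (median -0.67, camera adjusted p = 0.215), with KIF20B at -2.21 and CDC20 at 1.01 in the authors' deposited table. DNA replication genes had 6 rises and 10 falls among 36 (camera adjusted p = 0.303), with CDT1 at 2.07 and GINS4 at -1.23 in the authors' deposited table. Glycolytic genes had 11 rises and 0 falls among 19 (median 0.40, camera adjusted p = 0.116), with SLC2A1 at 1.31 and GPI at 1.14 in the authors' deposited table. Endoplasmic reticulum folding and translocation genes had 16 rises and 11 falls among 40 (camera adjusted p = 0.17), led by CALR at 1.87 and SSR4 at 2.27 in the authors' deposited table. Kinase signalling genes had 9 rises and 21 falls among 45 (camera adjusted p = 0.742), although MAPK3 and ARAF stood at 2.13 and 2.29 in the authors' deposited table. Translation factors had 14 rises and 18 falls among 50, with a median of -0.04 and a mean of 0.05 (camera adjusted p = 0.273). EIF4EBP1, a repressor of cap-dependent translation, and EIF5A stood at 3.07 (SE 0.11) and 2.21 (SE 0.11) in the authors' deposited table. Cytoplasmic long noncoding RNAs had 8 rises and 5 falls among 19 (camera adjusted p = 0.116), with DANCR at 2.16 and SNHG16 at 1.53 in the authors' deposited table. Short structured RNAs had 9 rises and 10 falls among 26, with a median of 0.00, a mean of -0.32 and a downward test (camera adjusted p = 0.31). RNU6ATAC and the signal recognition particle RNA RN7SL2 stood at -2.92 and -2.11 in the authors' deposited table.

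**Figure D2:**
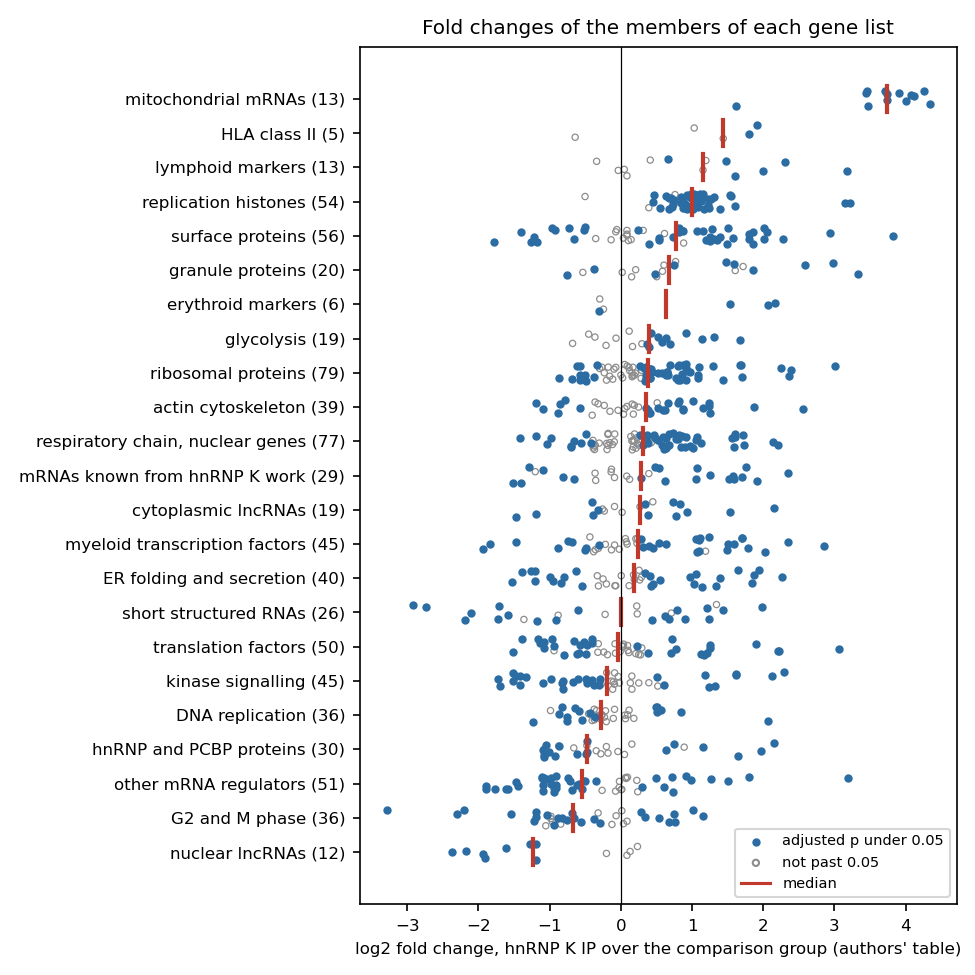
Log2 fold change (x axis, hnRNP K IP over the comparison group, from the authors' deposited table) of each tested member of the 23 gene lists (rows, number tested in brackets). Filled points have an adjusted p under 0.05, open points do not, and red lines are medians, from 3.74 for mitochondrial mRNAs to -1.24 for nuclear long noncoding RNAs.

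Adjusted over the list alone, the counts of rises and falls were 46 and 11 for ribosomal protein mRNAs, 51 and 0 for histones, 20 and 6 for actin genes, 11 and 29 for other mRNA regulators and 14 and 19 for translation factors. They were 10 and 6 for cytoplasmic long noncoding RNAs, 5 and 0 for lymphoid, 3 and 0 for erythroid and 1 and 0 for HLA class II genes, and those of the remaining lists were equal to the counts over all genes. The p-values of single genes are the authors' own, and those of lists come from camera on their statistic. With an estimated correlation 0 of the 23 lists were called, at a lowest adjusted p of 0.691 (0 lists at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 12. Of the 11 called lists, 9 could be set against protein-coding genes of the same genomic length, without mitochondrial mRNAs and nuclear long noncoding RNAs. The surface protein list alone kept its call there, with a median 0.72 above genes of the same length. Camera adjusted p was 0.228 for actin genes, 0.333 for other mRNA regulators, 0.341 for granule proteins and for nuclear respiratory-chain genes, 0.44 for myeloid transcription factors, 0.506 for lymphoid genes and 0.783 for ribosomal protein genes. The medians of ribosomal protein and respiratory-chain genes were 0.26 and 0.09 below those of genes of the same length. By the median, their rises are thus no larger than short genes show in general. The camera test leaned upward in both lists without passing, so median and test statistic differ in direction. Without the length step, camera over the same genes called 6 of these lists. Actin, myeloid factor and lymphoid lists missed the threshold there already (camera adjusted p = 0.115, 0.211 and 0.314), so their loss does not show an effect of length. The medians of actin genes and myeloid factors were 0.40 and 0.27 above those of genes of the same length. Fold changes are relative to the authors' size factors, because scaling by ERCC spike-ins shifted the median log2 fold change of recovered genes by -3.95.

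**Figure D3:**
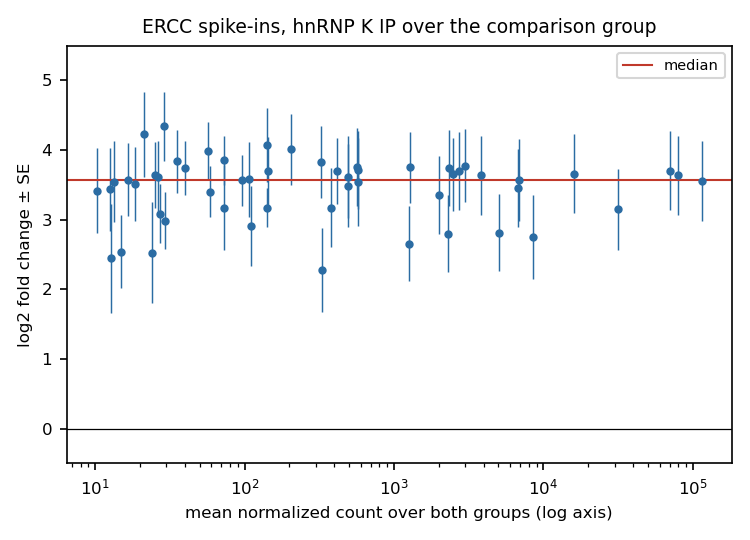
Log2 fold change (y axis, hnRNP K IP over the comparison group, with the SE as bars, from the authors' deposited table) of ERCC spike-ins against their mean normalized count over both groups (x axis, log scale). The 54 spike-ins lie between 2.28 and 4.34, around a median of 3.57 (red line), all above 0, and these values are shrunk toward 0.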

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

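Both tests of the spike-ins were chosen only after their values were seen. ERCC spike-ins, which the counts of genes in the main comparison leave out, were far higher in the hnRNP K IP than in the comparison group. Over 54 spike-ins with a mean of at least 10, the median log2 fold change was 3.57, with a range of 2.28 to 4.34, and 67 of 70 tested spike-ins passed an adjusted p of 0.05 upward while 0 passed downward in the authors' deposited table. These fold changes are shrunk toward 0, and the plain log2 ratios of the means in the authors' deposited table had a median of 4.19 over the same spike-ins (18.2-fold), with a range of 2.77 to 5.44. Spike-ins made up 2.20% of the summed signal of the hnRNP K IP and 0.157% of that of the comparison group. Reads per library were recovered in both groups for 77 of the 85 spike-ins above 0, without the most abundant ones, which leaves 8.66% of the spike-in signal of the hnRNP K IP and 10.5% of that of the comparison group. The normalized counts of this part came to 46134, 88193 and 45905 in hnRNP K IP libraries a, b and c and to 7526, 2246 and 2577 in the comparison libraries. The ratio of the group means of these sums, 14.6, depends on single libraries: it was 24.9 without comparison library a and 11.2 without hnRNP K IP library b, the lowest with any library left out. Of 23214 genes, 43 had a log2 fold change above the spike-in median of 3.57 in the authors' deposited table. Shrinkage was unequal, so this count may be too high: MT-CYB moved only from a plain 3.95 to 3.91, where the spike-in median moved from 4.19.

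The spike-ins did not all shift by the same factor. Over 20 spike-ins with recovered reads and a comparison mean of at least 20, the SD of the log2 shifts was 0.525, above the highest of 1000 simulations with counting error alone (0.157), which argues against counting error. The spread was 0.395 of that of genes at the same depth (95% bootstrap 0.243 to 0.485). A preparation bias that spread both sets equally would thus not be the whole of the spread of gene fold changes. A bias that acts by length or base content could spread genes more than spike-ins, which were not matched for these. The ratio therefore cannot exclude such a bias. Whether all libraries received the same mix is not given in the sources used here. Different mixes could shift spike-ins unequally by design, so part of the spike-in spread stays open. A lower yield of cell RNA per unit of spike-in in the hnRNP K IP stays open, since the amount added is not given in the sources used here, and no biological explanation was tested.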

How the results depend on the processing

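The fits to recovered reads, apart from the pseudocounts, the unfiltered fit and the left-out libraries, and also the readjusted p-values and the gene length tests were chosen after seeing the data. No paired analysis was possible because the deposited columns are group means and the recovered libraries carry no replicate number. The edgeR, DESeq2 and 9-library fits planned for counts, the control IP comparison apart from the input, their overlap and the motif test were not run. Against 12419 genes in the authors' deposited table, limma on recovered reads called 10293 (4945 higher, 5348 lower), and between 8799 and 11049 with each library left out in turn, the highest without hnRNP K IP library b. Requiring at least a 2-fold change left 7335 (3548 higher, 3787 lower), by construction. Scaling by ERCC spike-ins left 1 higher and 14976 lower, and it shifted the median by -3.95, where upper-quartile scaling shifted it by 0.12 and gave 5404 higher and 4814 lower. Camera called 11 lists on the deposited statistic, 0 with an estimated correlation, 8 on limma of recovered reads, 5 with at least 50 reads in 3 libraries, 6 with ERCC scaling, 7 without structured and mitochondrial RNAs and 5 with voom quality weights. In the fit without structured and mitochondrial RNAs, the mitochondrial list had no members and could not be called, by construction. It called 6 of 19 lists over protein-coding genes with a length and 1, the surface proteins, against genes of the same length. Left-out libraries gave 5 to 8 lists, with 5 without hnRNP K IP library a and 6 without library b or comparison library c. The cause was not tested, beyond fewer members in the recovered fits (8 of 79 ribosomal protein mRNAs). The ribosomal, myeloid factor and actin lists lost their call in each of the 16 refits to recovered reads. No named gene turned its direction in a call, ERCC scaling left aside, and no list did. Of values for named genes under other settings, 1018 kept their direction and side of the threshold and 41 fell short of it, in CA2, CD74, MAPT, MT-ND6, NDRG1, SERPINB1 and TERT. Depth limits HLA class II, ALOX15 and MT-ND6, with few reads per library.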

Other observations

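The tests of gene families, of nuclear RNA, of the mitochondrial strands and of lists against genes of the same length were chosen only after values were seen. Predictions for the tests of level, of library b and of the splits were written before their results. None of these tests was in the original design. Those of library b and of the splits use recovered reads, an alternative chosen after seeing the data. Zinc finger genes with ZNF symbols were lower as a family in the authors' deposited table: 305 of 514 fell and 95 rose, with a median log2 fold change of -0.71 (camera adjusted p = 7.95e-06, and adjusted p = 0.881 with an estimated correlation). These family tests did not allow for gene length. The rise of ZNF358 went against that family. Golgin genes of the GOLGA8 group fell in 13 of 17 members and rose in 0, with a median of -1.62 (camera adjusted p = 7.95e-06, and adjusted p = 0.797 with an estimated correlation), and these near-identical copies share reads. Antisense long noncoding RNAs rose in 186 of 562 and fell in 62 (camera adjusted p = 0.176), and mitochondrial ribosomal protein genes rose in 31 of 90 and fell in 27 (camera adjusted p = 0.318). Proteasome subunits rose in 9 of 57 and fell in 20 (camera adjusted p = 0.318). The other families tested also missed the threshold, at camera adjusted p of 0.776 for SNORA, SNORD, LINC and aminoacyl-tRNA synthetase genes and 0.96 for SCARNA genes. By chromosome, protein-coding genes had the highest median log2 fold changes on 19 (0.67), 22 (0.54), 16 (0.43) and 17 (0.40) and the lowest on 13 (-0.62), 4 (-0.46), 5 (-0.39) and 18 (-0.39). These medians were not adjusted for gene length or base content, so they do not show an effect of the chromosome itself.

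mRNAs of long genes were lower in the hnRNP K IP. The 2714 shortest protein-coding genes, with a median genomic length of 5020 bases, had a median log2 fold change of 0.69 with 1497 rises and 274 falls, and the 2714 longest, at 162818 bases, had -0.40 with 434 rises and 1188 falls in the authors' deposited table. Level does not account for it: with the mean level held fixed, the partial rank correlation of length with log2 fold change over 13567 genes was -0.366 (-0.366 without), and genes are not independent replicates. More nuclear RNA in the comparison group may contribute, as nuclear long noncoding RNAs fell, but SNORA, SNORD and SCARNA genes had a median log2 fold change of -0.0141 (95% bootstrap -0.24 to 0.14), which leaves it open. Some gene lists moved with length. Of the 9 called lists that could be tested, camera called 6 over protein-coding genes and 1 against genes of the same length. Ribosomal protein genes, with a median length of 5011 bases, had a median fold change 0.26 below that of genes of the same length on the log2 scale. Actin, myeloid factor and lymphoid lists had missed the threshold before the length step. It left the medians of actin genes (0.376 before, 0.402 after) and myeloid factors (0.255 and 0.267) about the same. Loss of long or GC-poor fragments in library preparation was not tested, for lack of sequences, and a preference of hnRNP K stays open as untested.

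hnRNP K IP library b stood apart from a and c. Its correlations with them over 15303 genes were 0.973 and 0.974 (log2 scale), where a and c reached 0.989 and comparison libraries 0.992 to 0.993, and its voom quality weight was 0.160. Fewer reads do not account for it, since library a thinned to 89.4% of its reads kept a correlation of 0.989 with library c. Its deviation from a and c followed the difference of a and c from the comparison group (Spearman's rho 0.510 across 10867 genes). Library b is thus consistent with a stronger version of the same change, which could be a cleaner IP or a stronger preparation bias, and these cannot be separated here.

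A hypothesis from the C-rich preference of hnRNP K is that mitochondrial RNAs read from the heavy strand, which are C-rich, rise more than those read from the light strand. Over 24 heavy-strand and 5 light-strand RNAs with at least 10 reads, mean log2 ratios were 3.56 and 2.13, a difference of 1.43. RNAs of a strand are cut from shared transcripts and are not independent, and the comparison was chosen after MT-ND6 was seen, so the p-value of its permutation test is not given. The light-strand RNAs all had few reads, and among RNAs with under 1000 reads the difference was 1.09 over 10 and 5, so level may account for part of it and strand cannot be told from it here.

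With 3 libraries against 3 there are 10 splits of the 6, too few for a share under 0.05. Of these, 1 split, the real grouping, called 10293 genes by limma, and the highest of the other splits called 0.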
